A study of Ovis aries with 6 samples.

How the data were processed

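Gene expression was measured in dorsal skin of Hu sheep lambs (Ovis aries) at 2 days of age, in 3 lambs with a large wave coat pattern and 3 with a small wave pattern. Per the labels' protocols, total RNA was amplified, labelled with Cy3 and hybridised to one-colour arrays, 1 lamb per array. The series' design text states that the lambs shared a sire and that each pair of a large wave and a small wave lamb shared a dam. All 6 arrays lay on 1 slide and were scanned once, so neither slide nor scan differed between the groups.

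The authors' scanner files hold spot intensity values written by Agilent Feature Extraction, version 10.7.3.1 per the file headers (10.7 per the submitters' processing notes), for array design 019921. The processed signal used as the main value is an intensity from which Feature Extraction had subtracted the background, per the file headers; it was not scaled between arrays. The authors' deposited value table holds log2 values for 15068 rows with a median of 4.95 in each of the 6 columns. It correlated with quantile-normalised log2 processed signals at r = 0.99999 or above in each array, across probes, which are not independent replicates. Its normalization is not given in the sources used here, and it entered as an alternative.

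From the scanner files, the log2 processed signal was taken minus each array's 75th percentile of it over the 15208 spots without controls. Spots of one probe were averaged, spots that Feature Extraction marked as outliers were left out, and saturated spots would have been kept, of which there were 0. The 15008 probes were reduced to 10048 that were well above background on at least 3 of the 6 arrays, and 1 of these had no value left in one group, so that 10047 were tested. Outlier marks fell mostly on bright probes: with the kept probes in 10 classes of equal size by signal, 36.1% had at least 1 marked array in the brightest class and 0% in the dimmest. The 75th percentile of the signal ranged from 94.7 to 391.5 between arrays, and 51.4 to 70.7% of spots were well above background. For arrays, the number of arrays per group limits the precision: the 95% confidence interval of a probe's difference reached a median of 1.06 to either side on the log2 scale.

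Groups were compared as large wave minus small wave with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Gene names came from the RefSeq accessions on the array, matched without versions to the reference table of assembly ARS-UI_Ramb_v3.0; 767 of 786 such probes matched, giving 500 genes, of which 346 had a tested probe. All other probes are unnamed here. A gene was represented by its kept probe with the highest mean. No genome was used, so no coordinates are given.

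Before the data were examined, 39 gene lists for newborn skin were written down; a few alias clashes and respellings were corrected by hand afterwards. Lists were tested with camera at a preset correlation of 0.01 where at least 5 genes had a value on all 6 arrays, with camera at an estimated correlation and fry beside it. The rule for named genes was also fixed before: since fewer than 20 named genes passed the threshold, up to 10 genes in each direction with the smallest unadjusted p, an absolute log2 difference of at least 1 and no overlap between the groups; and from each list described, up to 2 members higher and 2 lower by smallest unadjusted p. The rule took 3 higher and 8 lower genes, of which 1 is not reported here.

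The labels number the replicates 1 to 3 in each group. Deviations from the group means correlated at 0.30, 0.18 and 0.20 between the same-numbered lambs, each above the 0.1 set for pairing, so the numbers were taken to pair the lambs. No label states that the number marks the pair. Replicates 1, 2 and 3 of both groups lay in columns 2, 3 and 4 of the slide, so a shared dam and a shared slide column cannot be told apart. The main model had no block, as fixed before the data were examined, and the block was an alternative.

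Alternatives fixed before were normexp background correction with offset 50 followed by quantile normalization, quantile normalization alone, the authors' deposited table, no filter on dim probes, a filter requiring all 6 arrays, the replicate block, the row of the slide as a block, leaving out each array, array weights, no variance trend, other thresholds, other set tests and the mean over a gene's probes. The normexp alternative had been planned on mean spot signals; median spot and background signals were used here. Its offset by itself makes log2 differences of dim probes smaller. Chosen after seeing the data were keeping the outlier-marked spots, array brightness as a covariate, named genes alone as background of the set test, and a preference for probes measured on all 6 arrays.

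The model was tested on simulated data with the spread of the 9220 probes measured on all arrays and 200 changed probes. At the adjusted threshold it recovered 2.99% of probes changed 2-fold, 31.3% of those changed 4-fold and 78.8% of those changed 8-fold, with 2 false calls among 77. With the replicate block, 0 of 67, 14 of 67 and 50 of 66 were recovered, in arrays simulated without pairing. Of 50 simulated lists of 10 genes shifted by 1 on the log2 scale camera called 50, and of 50 lists not shifted it called 1. All probes were drawn independently, so a correlation between the genes of a list was not simulated. In the real data camera estimated it at 0.38 for the interferon response list, and most lists tested had fewer than 10 genes. These counts may therefore not carry over to the lists tested here. The probe simulation likewise held no component shared between probes. In the real data the first principal component held 42.8% of the variance and followed array brightness. The shares recovered and the false calls may therefore differ in the real arrays.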

Results

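Skin of newborn Hu lambs was profiled on 6 arrays, 3 from lambs with a large wave coat and 3 from lambs with a small wave coat, to compare the expression of hair follicle genes between coat patterns. Hu sheep are a Chinese breed valued for the wavy fleece of its newborn lambs. The 75th percentile of the signal, which measures how bright an array was, was 391.5, 204.7 and 249.2 in large wave replicates 1 to 3 and 284.8, 152.2 and 94.7 in small wave replicates 1 to 3. The share of spots well above background was 70.7, 61.1 and 68.2% in the large wave arrays and 69.4, 57.3 and 51.4% in the small wave arrays. In each of the 3 same-numbered pairs the large wave array was the brighter one.

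No named gene passed the adjusted threshold between large wave and small wave skin. Of 346 named genes, 139 had higher and 207 lower values in large wave skin, and the differences below are given as values with their errors (n = 3 arrays per group unless stated). Probes that do not represent their gene had smaller unadjusted p in some cases, as for MT3 below. Among the representing probes the smallest was that of AQP1, a water channel. Its log2 scaled signal averaged -3.34 ± 0.26 in large wave and -1.04 ± 1.44 in small wave skin (SD), a difference of -2.29 ± 0.70 (SE, 95% confidence interval -3.91 to -0.68, adjusted p = 0.777). This is 4.90-fold between the group means, and 1 array contributes much of it: without small wave replicate 3, at 0.43 against -2.45 and -1.12 in the other small wave arrays, the difference was -1.55. Over the alternatives it ranged from -2.99 to -0.94, the latter after normexp correction, and its other probe gave -1.62. PADI3, a peptidylarginine deiminase that modifies trichohyalin in the inner root sheath, was 2.06-fold higher in large wave skin, with a difference of 1.04 ± 0.35 (95% confidence interval 0.23 to 1.86, adjusted p = 0.777). Its 3 large wave arrays all lay above the 3 small wave arrays, and its second probe gave 1.16; after normexp correction the difference was 0.49, the lowest of its alternatives.

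**Figure D1:**
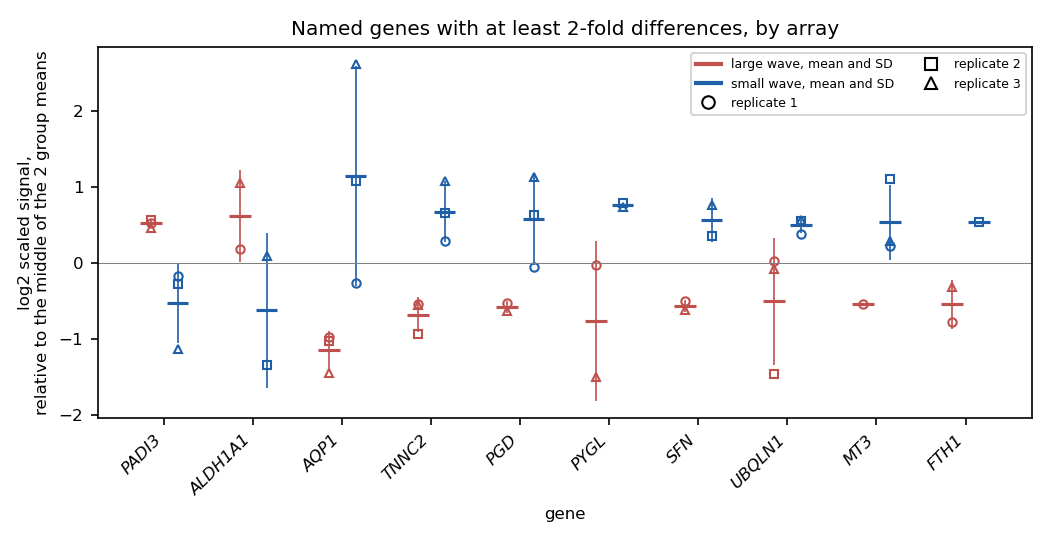
Log2 scaled signal of 10 named genes with at least 2-fold differences and no overlap between groups, drawn relative to the middle of the 2 group means (y axis) for each gene (x axis); points are arrays, horizontal lines group means and vertical lines SDs. AQP1 has the widest gap, 2.29 on the log2 scale. MT3 has 1 large wave array and FTH1 has 1 small wave array with a value, and SFN has the opposite sign after normexp correction. PGD, PYGL, SFN, ALDH1A1, MT3 and FTH1 lack a value on at least 1 array, which makes no overlap more frequent by chance. For ALDH1A1, PYGL, SFN and FTH1 the arrays drawn set bright large wave arrays against dim small wave arrays. For MT3 the large wave array drawn is brighter than each small wave array.

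The other genes given under the rule had differences between 1.01 and 1.53 on the log2 scale, each with adjusted p = 0.777. In the higher direction, ALDH1A1, which makes retinoic acid, had a difference of 1.24 ± 0.60 (SE) over 2 large wave and 2 small wave arrays, 0.52 without small wave replicate 2, and 3.63 with array brightness as a covariate. In the lower direction, TNNC2, a troponin C of fast skeletal muscle, differed by -1.35 ± 0.43, with 2 of 3 large wave arrays well above background, and its other probe by -0.54. PGD, an enzyme of the pentose phosphate pathway, differed by -1.15 ± 0.42 (2 large wave arrays) and by -0.51 at its other probe. PYGL, a glycogen phosphorylase, differed by -1.53 ± 0.56 (2 arrays per group), by -0.27 at its other probe, by -0.78 without large wave replicate 3 and by -3.07 with array brightness as a covariate. After normexp correction TNNC2 had -0.30, PGD -0.60, PYGL -0.18, MT3 -0.57 and FTH1 -0.023. SFN, the epidermal 14-3-3 protein stratifin, differed by -1.12 ± 0.45 (2 arrays per group) and by 0.12 after normexp correction. UBQLN1, which links ubiquitinated proteins to the proteasome, differed by -1.01 ± 0.45, by -0.65 after normexp correction and by -0.53 without large wave replicate 2. The metallothionein MT3 differed by -1.07 ± 0.52 with 1 large wave array, and its other probe by -1.63 ± 0.32. In limma that other probe had a smaller unadjusted p (0.0017) than the AQP1 probe (0.012), and an adjusted p of 0.777. The ferritin heavy chain FTH1 differed by -1.08 with 2 large wave arrays and 1 small wave array, so no spread of the small wave group stands behind its adjusted p. Its other probes differed by -0.57 and, with the opposite sign, 0.98. For 4 of these genes, ALDH1A1, PYGL, SFN and FTH1, the large wave arrays with a value were all among the 3 brightest arrays and the small wave arrays with a value all among the 3 dimmest, so that coat pattern and brightness cannot be told apart in their differences. In MT3 the large wave array with a value was brighter than each small wave array. In KRT33A, KRT35, V15 and IGF2, given below, each large wave array with a value was likewise brighter than each small wave one. The same limit holds for the differences of these genes. SFN had -0.23, FTH1 -0.44 and PGD -0.75 after quantile normalization.

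Over all 10047 probes, 0 passed the adjusted threshold of limma in either direction, with a lowest adjusted p of 0.777. At an unadjusted p under 0.05 there were 384 probes, 155 higher and 229 lower in large wave skin, where 5% of the probes tested would be 502. After normexp correction and quantile normalization there were 377, 215 higher and 162 lower. The groups did not overlap for 1122 probes, 11.2%, where chance gives 11.4% given the arrays with a value, and for 900 of the 9220 probes with a value on all 6 arrays, 9.76%, where chance gives 10%. For the 827 probes with a value on fewer than 6 arrays it was 26.8%, where chance gives 26.9%. The no-overlap rule for named genes therefore takes genes with missing arrays more readily. These chance shares take all orders of the arrays as equally likely. Shares for lambs that are alike within pairs were not computed. Adjusted over the named genes alone the lowest p was 0.711 and 0 passed. With the replicate number, taken to pair the lambs, as a block, 0 probes passed and 577 had an unadjusted p under 0.05. This unadjusted count was 2172 with array weights, 142 with the row of the slide as a block, 252 with array brightness as a covariate, and 1762 without small wave replicate 1, 155 without large wave replicate 3 and 198 without small wave replicate 3. Without small wave replicate 1, each large wave array was brighter than each small wave array left. Coat pattern and brightness can therefore not be told apart in the 1762. The median size of the difference over probes was 0.40 on the log2 scale, 0.16 after normexp correction and 0.29 with array brightness as a covariate. Of the 37 genes named here, 27 had a difference over 1.5 times smaller after normexp correction and 16 with the covariate. The normexp setting adds an offset of 50 before log2, where array median signals were 12.4 to 64.4. The offset by itself makes differences of dim probes smaller, so smaller values there cannot decide whether such a difference holds. After quantile normalization alone the median size was 0.38, and 11 of the 37 genes were over 1.5 times smaller. The offset's share was not tested.

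Structural genes of the hair shaft had members on both sides. Of the 6 hair keratins measured, 2 had higher and 4 lower values in large wave skin, but at the same probes 6 of 6 were higher in the authors' deposited table, 4 after quantile normalization, 4 after normexp correction and 3 with outlier-marked spots kept. None passed, also when adjusted over the list alone. The mean over the 6 was -0.36, and 0.50 in the authors' table. KRT35 differed by -0.98 ± 0.36 (SE, 2 small wave arrays with a value) but by 0.50 in the authors' deposited table and by 0.13 with outlier-marked spots kept. V15, the reference table's symbol for keratin 31, differed by -0.58 ± 0.40 (2 small wave arrays), but by 0.13 after quantile normalization, by 0.50 after normexp correction and by 0.47 in the authors' table. KRT33A had 0.34 with 1 large wave and 2 small wave arrays, which leaves no spread in the large wave group, and 0.33 to 1.10 over the alternatives. Keratin 38 (K38) had 0.21 ± 0.93. Hair keratins lie among the brightest probes, where outlier marks are most frequent, and the list had under 5 genes with a value on all arrays, so it was not tested as a set in the main setting. With each gene's brightest probe chosen anew, 5 of 6 were higher in the authors' table, with a mean of 0.36 (camera adjusted p = 0.625), and 2 of 6 with marked spots kept (mean -0.014, camera adjusted p = 0.750). Both measured keratin-associated proteins, which cross-link hair keratins, had higher values, KRTAP4.3 by 0.78 ± 0.53 and KRTAP5.4 by 0.33 ± 0.28. Of the 4 inner root sheath genes 1 was higher (PADI3, above) and 3 lower, 2 and 2 after normexp correction; among these KRT25 differed by -0.80 ± 0.71, its second probe by 0.38, and the transcription factor GATA3 by -0.48 ± 0.39. In the hair matrix and cortex regulators list GATA3 and BMP4 went opposite ways, and of 3 dermal papilla genes 1 was higher. With array brightness as a covariate the genes with higher values were 1 of 6 hair keratins, 1 of 2 keratin-associated proteins, 2 of 4 inner root sheath genes and 2 of 3 dermal papilla genes. KRTAP4.3 had 0.26, KRTAP5.4 0.19 and GATA3 -0.13 without small wave replicate 3, and KRT25 had -0.10 without large wave replicate 2.

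**Figure D2:**
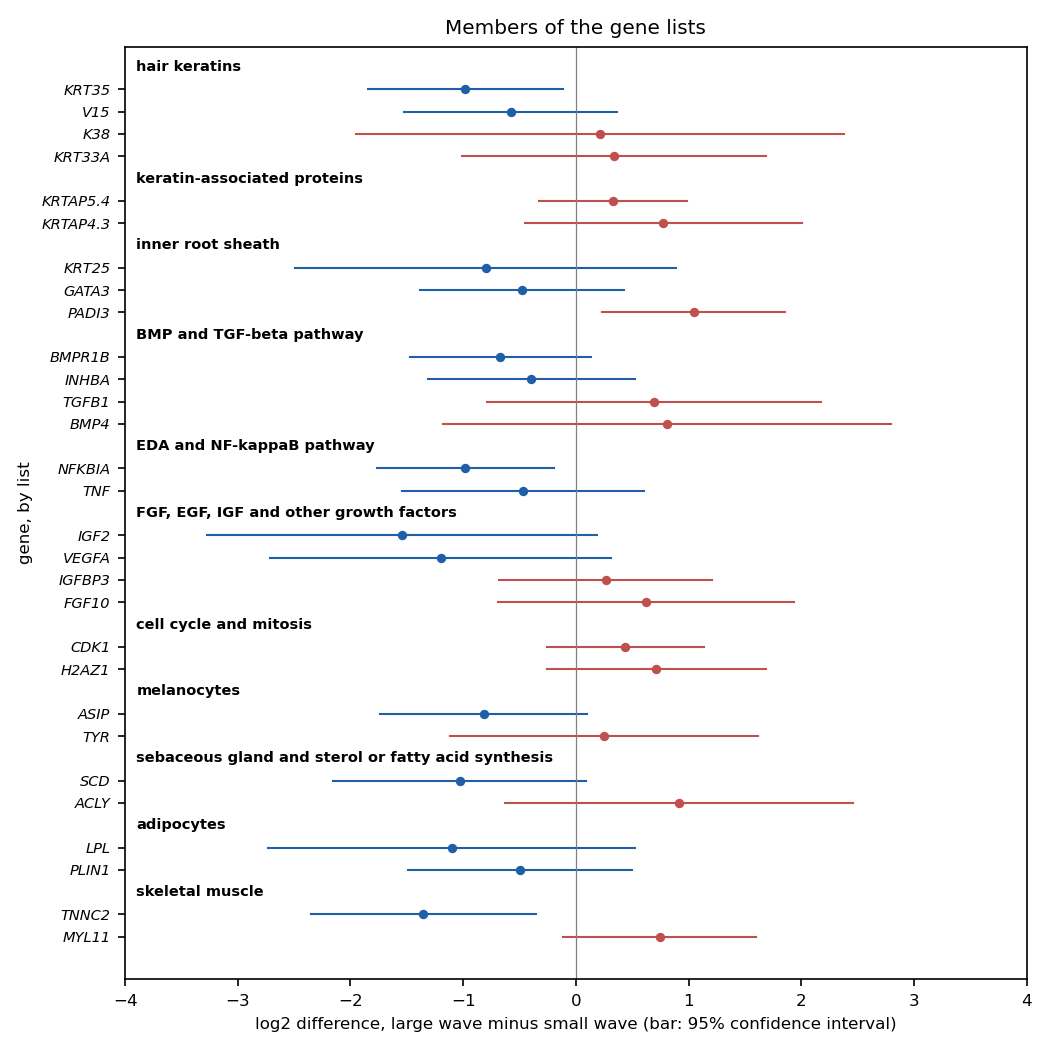
Log2 difference, large wave minus small wave (x axis), with its 95% confidence interval for the named members of 11 gene lists (y axis); red is higher and blue lower in large wave skin. The intervals of KRT35, PADI3, NFKBIA and TNNC2 leave out 0 before adjustment, and none of the genes drawn passed the adjusted threshold; the signs of KRT35, V15, IGFBP3 and TYR turn under another scaling or the authors' table.

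Signalling genes of the follicle also had members on both sides. In the BMP and TGF-beta pathway, 2 of 5 measured genes were higher and 3 lower (camera adjusted p = 0.740, adjusted p = 0.773 with an estimated correlation). The list's mean was 0.04, its median -0.23, and camera's direction lower. BMP4 had 0.81 ± 0.86 and TGFB1 0.69 ± 0.64, each well above background on 2 of 3 small wave arrays, and BMPR1B, a BMP receptor, had -0.67 ± 0.35 and INHBA -0.40 ± 0.40. Among growth factors 4 of 12 were higher and 8 lower, with a mean of -0.34 over the 10 tested (camera adjusted p = 0.397, adjusted p = 0.723 with an estimated correlation). IGF2 differed by -1.54 ± 0.73 (2 small wave arrays) and by 0.76 at its other probe, and VEGFA by -1.20 ± 0.65. FGF10, well above background on 2 large wave arrays and 1 small wave array, had 0.62 ± 0.57, and IGFBP3 had 0.27 ± 0.41 and -0.03 after normexp correction. NFKBIA, the inhibitor that holds NF-kappaB in the cytoplasm, differed by -0.98 ± 0.34 and TNF by -0.47 ± 0.46. NFKBIA did not pass over all probes (adjusted p = 0.777). Adjusted over the list alone, which had 2 measured genes, its adjusted p was 0.041, but it was under the threshold in 6 and not in 10 of 16 alternatives (adjusted p from 0.013 to 0.512). Among the latter were normexp correction, where its difference was -0.16 (adjusted p = 0.512), the replicate block (adjusted p = 0.060) and the authors' deposited table (adjusted p = 0.053). Among the former, both filter settings and marked spots kept gave the difference of the main fit, -0.98, and so add little. Over 32 lists with a measured gene, NFKBIA and SFN were the only genes under the threshold when adjusted over their list alone. After normexp correction VEGFA had -0.30, IGF2 -0.63, TNF -0.20, INHBA -0.20, BMPR1B -0.43, TGFB1 0.16, BMP4 0.48 and FGF10 0.12. With array brightness as a covariate VEGFA had -0.18, NFKBIA -0.62 and BMP4 -0.25. Without small wave replicate 3 VEGFA had -0.64, IGF2 -0.98, BMP4 0.024, TGFB1 -0.023, INHBA -0.065, TNF -0.23 and IGFBP3 0.015. FGF10 had 0.21 without large wave replicate 3. SFN was the only measured gene of the epidermal list, so its adjusted p over the list alone, 0.050, is its unadjusted p.

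Among other skin components, all 6 adipocyte genes had lower values in large wave skin, with a mean of -0.48, and 5 of 6 did after quantile normalization and in the authors' table. The mean was -0.12 after normexp correction and -0.30 without small wave replicate 3. This was the smallest p among the 8 lists tested (camera adjusted p = 0.180, adjusted p = 0.723 with an estimated correlation, adjusted p = 0.394 with fry), and 0 lists passed by any of these tests. LPL, lipoprotein lipase, had -1.10 ± 0.70, well above background on 2 arrays of each group, and PLIN1, perilipin, -0.50 ± 0.43, with its second probe at 0.04. PLIN1, and TYR given below, were well above background on 2 of 3 small wave arrays. Of the 6 sebaceous and lipid synthesis genes 1 was higher, ACLY by 0.92 ± 0.67, and 5 were lower, among them the desaturase SCD by -1.03 ± 0.48 (3 of 6 were higher in the authors' table; camera adjusted p = 0.596, adjusted p = 0.723 with an estimated correlation). Of 4 skeletal muscle genes 1 was higher, the myosin light chain MYL11 by 0.74 ± 0.37, and 3 lower, TNNC2 among them. Of the 2 pigmentation genes measured, TYR, the key enzyme of melanin synthesis in pigment cells, had 0.25 ± 0.59 (and -0.03 after normexp correction), and ASIP, the secreted agouti signal that antagonises the melanocortin receptor of pigment cells, -0.82 ± 0.40. The 3 cell cycle genes were all higher, H2AZ1 by 0.71 ± 0.42 and CDK1 by 0.44 ± 0.30. After normexp correction LPL had -0.088, PLIN1 -0.14, SCD -0.64, MYL11 0.40 and CDK1 0.13, and H2AZ1 had 1.31. With array brightness as a covariate LPL had -0.40 and SCD -0.54. LPL had -0.48 without small wave replicate 3, PLIN1 had -0.25 without large wave replicate 3, and without small wave replicate 2 ACLY had 0.078, H2AZ1 0.39 and ASIP -0.47. Second probes had the sign of the first for KRT35 (-0.69), K38 (0.49), GATA3 (-0.58), BMP4 (0.20), INHBA (-0.76), VEGFA (-0.90) and ASIP (-0.80). None of these genes passed.

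Between arrays, the first principal component, 42.8% of the variance, ordered the samples as their brightness did. The groups overlapped on it, with small wave replicate 1 above large wave replicates 2 and 3, but within each of the 3 same-numbered pairs the large wave array had the higher score and was the brighter. The paired differences, large wave minus small wave in pairs 1 to 3, were 5.38, 35.8 and 109 in the score and 0.46, 0.43 and 1.40 in the log2 75th percentile (exact sign-flip permutation p = 0.25 for each, two-sided, the smallest that 3 pairs allow). Its score correlated with the log2 75th percentile signal at r = 0.964 (exact permutation p = 0.0014, two-sided) and rho = 1 (exact permutation p = 0.0028) over 6 arrays, the 1 correlation computed, and at r = 0.985 without small wave replicate 3 and large wave replicate 1. The median signal of the spike-in controls was 671, 685 and 452 in large wave replicates 1 to 3 and 576, 765 and 725 in small wave replicates 1 to 3. The 3 brightest arrays, large wave replicates 1 and 3 and small wave replicate 1, had lower spike-in medians (452 to 671) than the 3 dimmest (685 to 765). This relation was not tested. The median correlation of log2 values across probes was 0.920 between arrays of one group and 0.920 between arrays of different groups.

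**Figure D3:**
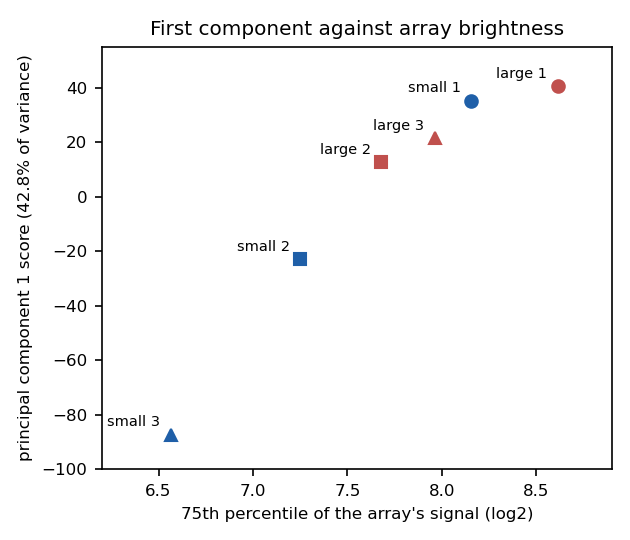
Score on principal component 1 (y axis, 42.8% of the variance) against the log2 75th percentile of each array's signal (x axis), 1 point per array, red for large wave and blue for small wave, with the replicate number. Small wave replicate 1 lies among the large wave arrays, and small wave replicate 3 is the dimmest, at 6.57.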

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

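The alternatives of keeping marked spots, array brightness as a covariate, named genes as the background, and a preference for probes measured on all 6 arrays were chosen after seeing the data; the others were fixed before. The count of probes past the adjusted threshold was 0 under each alternative fit, including each array left out, and 299 when the criterion was an unadjusted p under 0.05 with a fold of at least 2. The number of lists past the threshold was 0 under each of the alternatives, with lowest adjusted p values from 0.067 to 0.723. The replicate block changed no adjusted call; the count of probes at an unadjusted p under 0.05 went from 384 to 577 with the block. It was 142 with the row of the slide as a block, 2172 with array weights, 252 with array brightness as a covariate, and from 155 to 1762 with one array left out. The 1762 came without small wave replicate 1, where each large wave array was brighter than each small wave array left. Coat pattern and brightness cannot be told apart in that fit. The cause of these shifts was not tested. Array weights were lowest for small wave replicate 3 (0.381) and small wave replicate 1 (0.408). Of 37 named genes, 25 kept one direction under every alternative that gave them a value, and in 344 of 362 comparisons with other settings and 213 of 219 with one array left out the direction held; 0 passed the threshold. Of list means, 97 of 116 and 43 of 48 did. Some of these comparisons could not turn a sign, so the counts overstate how stable the directions were. Without the filter on dim probes, or with the filter requiring all 6 arrays, a gene's difference is that of the main fit. The replicate block leaves it unchanged for genes with a value on all 6 arrays. The other set tests and the named-gene background use the list means of the main fit. Signals not well above background on every array limit FGF10, LPL, TNNC2, BMP4, TGFB1, PLIN1 and TYR, and marked spots limit the hair keratins.

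Signs turned as follows; the cause was not tested. After normexp correction SFN had 0.12, V15 0.50, IGFBP3 -0.029 and TYR -0.027, and the list means were -0.013 for BMP and TGF-beta and -0.057 for cytokines. After quantile normalization V15 had 0.13 and cytokines -0.0094. In the authors' table KRT35 had 0.50, V15 0.47 and the sebaceous list 0.069. With marked spots kept KRT35 had 0.13. Without the filter BMP and TGF-beta had -0.090 and cytokines -0.30, and with the strict filter cytokines had -0.042. With the slide row as a block BMP and TGF-beta had -0.010 and cytokines -0.11, and with the mean over a gene's probes -0.079 and -0.11. With array weights BMP and TGF-beta had -0.10, the interferon list 0.20, K38 -0.23 and TYR -0.29. With brightness as a covariate, BMP and TGF-beta had -0.18, growth factors 0.0077, metalloproteinases 0.026, the sebaceous list 0.027, interferon 0.54 and cytokines -0.0037. In that fit K38 had -0.64, KRTAP4.3 -0.12, GATA3 0.052, BMP4 -0.25, INHBA 0.17, TNF 0.0011, IGFBP3 -0.061 and TYR -0.20. With one array left out K38 ranged from -0.39 to 1.30, TYR from -0.24 to 0.65, TGFB1 from -0.023 to 1.12, BMP and TGF-beta from -0.18 to 0.16, interferon from -0.59 to 0.32 and cytokines from -0.22 to 0.14.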

Other observations

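The counts over splits of the arrays and the tests of explanations in this part were chosen after the results were seen; the gene lists and set tests were fixed before. No immune or stress list passed the set test. Of 5 macrophage and MHC class II genes 1 was higher in large wave skin (camera adjusted p = 0.740, adjusted p = 0.773 with an estimated correlation), of 5 interferon response genes 1 (adjusted p = 0.789 and 0.926), of 7 cytokines and chemokines 5 (adjusted p = 0.961 and 0.972) and of 7 metalloproteinases and inhibitors 2 (adjusted p = 0.635 and 0.723). Lists with too few genes for the set test gave counts only: lymphocytes 2 of 4 higher, mast cells and granulocytes 2 of 3, immediate early and heat shock genes 3 of 4, oxidative phosphorylation 1 of 4, ribosomal proteins 1 of 3, cell cycle inhibitors 2 of 3. Both genes of the hypoxia list, both metallothionein and oxidative stress genes and both sweat gland genes were lower, and 1 of 2 dermal matrix genes was higher. The single genes measured for wound epidermis, endothelium and red blood cells were higher, and the 1 for smooth muscle was lower. Some of these counts turn with the scaling: after quantile normalization 1 of 2 genes was higher for hypoxia, for metallothioneins and for sweat gland, 2 of 4 for oxidative phosphorylation, 2 of 3 for ribosomal proteins and 3 of 3 for cell cycle inhibitors. After normexp correction 2 of 7 cytokines, 2 of 5 interferon genes, 3 of 7 metalloproteinases and both dermal matrix genes were higher, as was the smooth muscle gene, by 0.48. With array brightness as a covariate 0 of 4 immediate early and heat shock genes were higher (mean -0.25), 5 of 5 interferon genes (mean 0.54), 3 of 7 cytokines, 4 of 7 metalloproteinases, 2 of 5 macrophage genes, 2 of 3 ribosomal proteins, both dermal matrix genes and the smooth muscle gene, by 0.54. For hypoxia the mean went from -0.70 to -0.17 after normexp correction. The lists for Wnt, hedgehog and Notch signalling, follicle stem cells, nerve, mitochondrially encoded transcripts and sex-linked markers had no named probe here and were not analysed.

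Among the 10 splits of the 6 arrays into 3 and 3, the coat pattern gave 0 probes past the adjusted threshold and the highest other split 0, so all 10 gave as many. At an unadjusted p under 0.05 the pattern gave 384 and the highest other 1958, and 4 of the 10 splits gave as many as the pattern. For lists the pattern gave 0 and the highest other 2, so 10 of 10 gave as many. With 10 splits no share under 0.05 can be reached. The 4 splits that part all 3 pairs gave 384 (the pattern), 311, 166 and 64, and the others part 1 pair.

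The split with 1958 probes sets the 3 brightest arrays, large wave replicates 1 and 3 and small wave replicate 1, against the 3 dimmest, and points to a structure of the samples. Differences in the overall distribution of signals between arrays are argued against, since 1735 probes were left after quantile normalization, where the next split had 676. Quantile normalization does not remove effects of background or low signal on single probes. The normexp setting was not run on the splits, so such effects stay open. The share at an unadjusted p under 0.05 was 23.5% in the brightest of 3 equal classes of probes and 16.7% in the dimmest. These shares cannot decide on noise of dim probes, since noise raises the error and so can itself lower the share. Noise of dim probes therefore stays open. An exchange of the labels of large wave replicate 2 and small wave replicate 1 stays open as a candidate explanation: the split with both exchanged is this very split, with 1958 probes, so exchanged labels and brightness cannot be told apart here. Against an exchange, the deviations of same-numbered lambs correlated at 0.30 and 0.18 in pairs 1 and 2 as labelled and at 0.027 and -0.0080 with the labels exchanged, and large wave replicate 1 and small wave replicate 1 had the highest correlation of log2 values of any 2 arrays, 0.968. Same-numbered arrays also shared a slide column, and large wave replicate 1 and small wave replicate 1 were the 2 brightest arrays. Either could give such likeness whatever the labels, so the likeness does not exclude an exchange. The large wave array was the brighter in 3 of 3 same-numbered pairs (exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow), which leaves open whether brightness goes with coat pattern. Differences between the lambs or in RNA quality were not tested and stay open.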
